A study of Homo sapiens with 23 samples.

How the data were processed

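The series holds polyA RNA sequencing of 23 samples of C-33A and CaSki, a pair of established cervical squamous carcinoma cell lines. Cells were transfected with 100 nM of a microRNA mimic or of a negative control, per the labels. The 8 groups hold 3 samples each, except C-33A with the miR-124-3p mimic, which holds 2. The labels do not say whether samples of a group came from separate cultures, so p-values rest on the spread between these samples, which may be technical. Per the titles, replicate numbers recur across the groups of a line, and no step here pairs them.

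The submitters used FastQC 0.73, STAR 2.7.10b, featureCounts 2.0.3 and edgeR 3.36.0 with GRCh38 (hg38), per the submitters' processing notes. What was deposited and used here is 1 table for each of the 6 comparisons of a mimic with the negative control of the same line. Per the file headers, each deposited table gives a log2 fold change, an average log2 CPM, an F score, a p-value and an adjusted p-value (FDR) for 61217 genes, with no filter on expression. The deposited FDR equals a Benjamini-Hochberg adjustment of the deposited p-values over all listed genes. Values per sample are not analysed here, so the depth of each sample is unknown and no interval that needs it is given. The denominator degrees of freedom recovered from the deposited F score and p-value reached 183651 for C-33A with miR-124-3p and 244868 for the other C-33A comparisons. These equal 3 and 4 per listed gene, the residual degrees of freedom of 5 and of 6 libraries in 2 groups. The values recovered from the deposited CaSki tables were 31.52, 38.18 and 25.72 and follow no such rule. The C-33A p-values and recovered SEs therefore rest on a spread pooled over the listed genes, not on that of each gene alone. The CaSki degrees of freedom are far smaller, so the lines were not tested with the same degree of pooling. The strand setting of the read counting is not given in the sources used here, so antisense and overlapping genes are not singled out.

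A gene was called as risen or fallen at a deposited FDR under 0.05. The design fixed before the data were examined foresaw a fit to counts where values per sample were at hand, and the use of the deposited statistics otherwise; the second case applied. A standard error (SE) was recovered as the log2 fold change divided by the signed normal quantile of the deposited p-value. Named genes followed a rule that was part of this design. For each comparison these were the 8 largest falls and 8 largest rises among called protein coding genes with an average log2 CPM of 1 or more. The rule added up to 4 members with the lowest p in each gene list that passed or had called members counted in the text, up to 6 genes called alike in both lines for each microRNA, up to 4 that differed most between lines, and the published targets of the transfected microRNA. Genes outside the rule are said to be chosen after their values were seen.

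Sites for a microRNA were matches to positions 2 to 8 of its seed region in the 3' UTR of the longest protein coding transcript of GENCODE release 29 (GRCh38). An 8mer site is such a match followed by an A, and the genes compared with 8mer genes include those with other sites only. A 6mer site needs no match at position 8, so the 6mer genes include all genes with a longer site. Of the 61217 listed genes, 19035 had such a 3' UTR. The median log2 fold change of genes with a site was compared with that of genes without one, over genes with an average log2 CPM of 0 or more, by a two-sided permutation test over genes with 100000 draws. Its smallest possible p is 1e-05, genes are not independent replicates, and SEs of the difference came from 500 bootstrap draws. Benjamini-Hochberg adjustment covered all tests of the 3 site lists in the 6 comparisons. The 28 gene lists, put together from background knowledge and not from a database, were fixed before the data were examined. They were tested with cameraPR of limma 3.58.1 in R 4.3.3, with a preset inter-gene correlation of 0.01, in lists with at least 5 measured members, adjusted over all lists and comparisons. Of 720 list symbols, 3 were not among the listed genes. The results of 1 list are not reported here, though it is included in the adjustment and in the numbers of lists tested and passed. An estimated correlation needs values per sample and was not used here. Fold changes in the 2 lines were compared by a normal test of their difference with the recovered SEs. Pairs of mimics of a line share the control libraries, so 100 simulated sets of unchanged groups against shared controls are given beside each correlation.

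After the data were examined, a trend of the fold change with transcript length and GC content was fitted by a robust additive spline and subtracted, in 1 form only. A contrast of each mimic with the mean of the other 2 mimics of the line, in which the control libraries cancel, was also added then. Alternatives listed in the design changed the threshold, the set of genes adjusted over, the type of site, the 3' UTR length of the comparison genes, the correlation of the list test and the expression filter. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

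The steps were tested on simulated data, with the recovered SEs of the real genes, 100 genes changed by 1 and 100 by 2. For CaSki with miR-23b-3p, over 11717 genes, the test recovered 91 of 100 genes changed by 1 on the log2 scale and all 100 changed by 2. With the fitted trend added, 563 unchanged genes were called, and 4 after the trend was removed. The added trend had the same form as the fit that removed it, so this does not show how well a trend of another form is removed. For the difference between lines after miR-124-3p, over 12970 genes, 38 of 100 differences of 1 and 93 of 100 differences of 2 were recovered.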

Results

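Gene expression was measured by polyA RNA sequencing in C-33A, an HPV-negative cervical carcinoma line, and in CaSki, an HPV-positive line from a metastasis. Each line received 100 nM of a negative control or of a synthetic mimic of miR-218-5p, miR-23b-3p or miR-124-3p. The 23 samples form 8 groups of 3, except 2 samples of C-33A with miR-124-3p. The comparisons ask which transcripts changed with each microRNA and whether the lines responded alike. Values for genes come from the authors' deposited table of each comparison, so no values per sample and no sequencing depth are given.

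In C-33A with miR-124-3p, 80 genes fell and 19 rose at a deposited FDR under 0.05. In the authors' deposited table, the sialomucin CD164 fell by 1.5 on the log2 scale (SE 0.175, adjusted p = 8.12e-13) and ATL3, a shaper of endoplasmic reticulum tubules, fell by 1.45 (SE 0.177, adjusted p = 7.79e-12). The vesicle fusion protein VAMP3 fell by 1.33, the integrin beta subunit ITGB1 by 1.24 and the magnesium transporter MAGT1 by 1.22 in the authors' deposited table. Among the rises in the authors' deposited table were MAP2K6, a kinase upstream of p38, at 1.34, and CASTOR2, a regulator of mTORC1, at 1.24. Of 31 measured published targets of miR-124-3p, 10 fell, none rose, and 21 fell when adjusted over the list alone (median -0.64, adjusted p = 6.53e-39, cameraPR). The glycosyltransferase B4GALT1 (-1.11), the phosphatase CTDSP1 (-0.93), the lactate transporter SLC16A1 (-0.90) and the scaffold IQGAP1 (-0.82) were among the targets that fell in the authors' deposited table. ITGB1P1, a pseudogene of ITGB1 chosen after its values were seen, stood at -1.38 in the authors' deposited table, and reads may be split between the pair.

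Genes with a miR-124-3p site in the 3' UTR had a median log2 fold change 0.102 lower than genes without one (difference -0.102, SE 0.0088, permutation p = 1e-05, the smallest possible). The difference was -0.192 with 8mer sites and -0.015 with 6mer sites, a set that includes the longer sites. Of 78 falls with an annotated 3' UTR, 60 held a site (76.9%), against 16.5% of other genes (Fisher's exact test, adjusted p = 3.29e-30). CD164 has 8mer sites on chromosome 6, whose matches to seed positions 2 to 8 lie at 109368194 to 109368200 and 109367193 to 109367199. VAMP3 has an 8mer site on chromosome 1, with the match to these positions at 7780082 to 7780088, beside shorter sites, all in 3' UTRs (GRCh38, GENCODE release 29). The RAS-MAPK list was lower (median -0.25, adjusted p = 4.05e-05): 1 of 27 members fell, and 5 when adjusted over the list alone. That member was EGR1, an immediate early transcription factor, at -1.22 in the authors' deposited table. The neuronal list was higher with 0 of 13 members called and 1 when adjusted over the list alone (median 0.37, adjusted p = 0.00599). Ribosomal protein genes had a median of -0.275 (adjusted p = 1.98e-08) with 0 of 29 called, and of -0.151 with the trend on length and GC content removed (adjusted p = 0.00288). The G1/S list (median -0.179, adjusted p = 0.0167) and the PI3K-AKT-mTOR list (median 0.186, adjusted p = 0.00865) passed with 0 members called, and neither passed with a correlation of 0.05 (adjusted p = 0.162 and 0.105) or with the trend on length and GC content removed (0.0503 and 0.428). In the ER stress and integrated stress response list 1 of 25 fell and 4 when adjusted over the list alone (median -0.086, adjusted p = 0.0218, and 0.162 with a correlation of 0.05); the member was TRIB3, at -1.01 in the authors' deposited table. Of 24 genes of the small RNA machinery 1 rose, TNRC6C, at 0.93 in the authors' deposited table, and 1 when adjusted over the list alone (median 0.077, adjusted p = 0.0242, 0.162 with a correlation of 0.05 and 0.0853 with the trend removed).

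In C-33A with miR-23b-3p, 19 genes fell and 10 rose. FAM234B fell by 1.36 in the authors' deposited table (SE 0.185, adjusted p = 8.03e-09), and the glycosyltransferase B4GAT1 fell by 0.99 and DDAH1, which degrades methylarginines, by 0.97 in the authors' deposited table. The ER stress and integrated stress response list was higher: 3 of 25 rose, none fell, and 11 rose when adjusted over the list alone (median 0.40, adjusted p = 1.87e-25, cameraPR). These were the pseudokinase TRIB3 at 1.32 (SE 0.180, adjusted p = 8.03e-09), the glutathione-degrading enzyme CHAC1 at 1.24 and the transcription factor DDIT3 at 1.03 in the authors' deposited table. STC2, a secreted glycoprotein, rose by 1.40, ADM2 by 1.52, the cyclin CCND3 by 1.02 and the transcription factor CEBPB by 0.92 in the authors' deposited table. The G2/M list was higher (median 0.18, adjusted p = 2.31e-06) with 0 of 36 members called.

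Of 18 falls with an annotated 3' UTR, 17 held a miR-23b-3p site (94.4%), against 21.6% of other genes (Fisher's exact test, adjusted p = 4.37e-10). The shift of genes with a site was -0.135 (SE 0.005, permutation p = 1e-05, the smallest possible), and -0.168 with 8mer sites, -0.101 with 6mer sites and -0.073 with the trend on length and GC content removed. FAM234B has 8mer sites in its 3' UTR on chromosome 12, whose matches to seed positions 2 to 8 lie at 13080883 to 13080889, 13083334 to 13083340 and 13083406 to 13083412 (GRCh38). Of 26 measured published targets, 0 were called, and 1 fell when adjusted over the list alone, while the list as a whole was lower (median -0.14, adjusted p = 0.00078).

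In C-33A with miR-218-5p, 42 genes fell and 4 rose. COMMD8 fell by 1.11 (SE 0.183), MOSPD1 by 1.08 and GLCE, an epimerase of heparan sulfate synthesis, by 1.01 in the authors' deposited table. The centrin CETN2 fell by 0.98 and BIRC5 (survivin), an inhibitor of apoptosis with a role in mitosis, by 0.87 in the authors' deposited table. ACVR2B, an activin receptor, rose by 0.89 in the authors' deposited table. Of 22 measured published targets, 4 fell, none rose, and 10 fell when adjusted over the list alone (median -0.42, adjusted p = 4.6e-13, cameraPR): VOPP1 (-0.96), BIRC5 (-0.87), the connexin GJA1 (-0.78) and STAM2 (-0.69) in the authors' deposited table. With the trend removed the list had a median of -0.244 and 3 falls (adjusted p = 1.38e-13). Genes with a miR-218-5p site shifted by -0.075 (SE 0.0069, permutation p = 1e-05, the smallest possible), and by -0.129 with 8mer and -0.025 with 6mer sites. Of 41 falls, 36 held a site (87.8%), against 15.6% of other genes. These falls also held miR-23b-3p sites more often (39.0% against 21.7%, Fisher's exact test, adjusted p = 0.0316), but not miR-124-3p sites (14.6% against 16.9%). The 3' UTR length was not matched in this comparison. All genes with a miR-23b-3p site shifted by -0.016 (permutation test, adjusted p = 0.00153), and by 0.001 with the trend removed (adjusted p = 0.741). The ER stress and integrated stress response list was higher (median 0.08, adjusted p = 1.7e-06) and the interferon list lower (median -0.36, adjusted p = 0.00129), with 0 members called in either. In the interferon list 2 members fell when adjusted over the list alone, and it did not pass at an average log2 CPM of 1 or more (adjusted p = 0.121); with the trend removed its median was -0.229 (adjusted p = 0.000499). In the G2/M list 1 of 36 fell, BIRC5, and 2 when adjusted over the list alone (median -0.092, adjusted p = 0.00078); with the trend removed the median was -0.027 (adjusted p = 0.0239). The mitochondrially encoded list was higher with 0 of 13 called (median 0.65, adjusted p = 0.0154, and 0.0706 with a correlation of 0.05).

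In CaSki with miR-124-3p, 187 genes changed, of which 63 rose and the others fell. VAMP3 fell by 1.41 (SE 0.198, adjusted p = 7.03e-08), CTDSP1 by 1.37, ATP6V0E1, a subunit of the vacuolar proton pump, by 1.37, ATL3 by 1.34 and ITGB1 by 1.32 in the authors' deposited table. ENO2, the neuronal enolase, rose by 1.48 (SE 0.287), the keratin KRT80 by 1.44 and SHROOM2, an actin-binding protein, by 1.16 in the authors' deposited table. Of 35 measured published targets, 12 fell, none rose, and 18 fell when adjusted over the list alone (median -0.39, adjusted p = 1.95e-22, cameraPR). SERP1 (-1.13), CD164 (-1.10), MAGT1 (-0.95), RHOG (-0.95) and CDK4 (-0.63) were among the targets that fell in the authors' deposited table. Genes with a site shifted by -0.063 (SE 0.0098, permutation p = 1e-05, the smallest possible), a shift that turned to 0.053 with 6mer sites and was -0.123 with 8mer sites, -0.134 with matched 3' UTR length, -0.146 with the trend removed and -0.127 against the other 2 mimics, and 91 of 120 falls held a site (75.8%), against 16.2% of other genes. In the neuronal list 1 of 15 members rose and 3 when adjusted over the list alone (median 0.295, adjusted p = 0.000864). In the PI3K-AKT-mTOR list 1 of 30 rose and 7 when adjusted over the list alone (median 0.201, adjusted p = 7.27e-05); with the trend removed it did not pass (median 0.109, adjusted p = 0.0853). Ribosomal protein genes had a median of -0.342 with 0 of 31 called (adjusted p = 7.34e-06), and of -0.192 with the trend removed (adjusted p = 0.0239). Of 28 published targets of miR-23b-3p 1 rose, and 5 rose and 2 fell when adjusted over the list alone (median 0.168, adjusted p = 0.00437). The list did not pass with a correlation of 0.05 (adjusted p = 0.0706) or with the trend removed (0.0683).

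In CaSki with miR-23b-3p, 609 genes fell and 863 rose. The transcription factor TFAP2A rose by 1.16 (SE 0.164, adjusted p = 8.46e-08), the citron kinase CIT by 1.15 and the acetyltransferase EP300 by 1.30 in the authors' deposited table. DDAH1 fell by 1.07 (SE 0.159, adjusted p = 3.16e-07), the histone genes H4C14 and H4C15 by 1.5 and 1.31, and the translation factor subunit EIF3C by 1.81 in the authors' deposited table. Of 31 ribosomal protein genes, 17 fell, none rose, and 20 fell when adjusted over the list alone (median -0.53, adjusted p = 8.08e-16, cameraPR), with RPS2 at -1.02 and RPL15 at -0.85 in the authors' deposited table. Histone H4 copies, EIF3C and ribosomal protein genes share sequence with paralogs or pseudogenes. Reads may be split between copies, which was not tested, so their values are uncertain. The mesenchymal list was higher: 7 of 20 rose, none fell, and 10 rose when adjusted over the list alone (median 0.38, adjusted p = 3.71e-05), with fibronectin FN1 at 0.94 and tenascin TNC at 0.68 in the authors' deposited table.

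Fold changes in this comparison followed transcript length: the median was -0.40 for transcripts under 1000 nt and 0.28 for those over 8000 nt, with a Spearman rho of 0.512 over 10323 genes with an average log2 CPM of 2 or more, which are not independent replicates. Genes with a miR-23b-3p site were higher, not lower, by 0.091 (SE 0.0087, permutation p = 1e-05, the smallest possible), and genes with miR-124-3p or miR-218-5p sites were higher by 0.121 and 0.140. The shift turned to -0.029 (permutation p = 0.00701) with genes matched on 3' UTR length, an alternative listed in the design. It was -0.053 with the trend on length and GC content removed, an alternative chosen after seeing the data. Of 544 falls with an annotated 3' UTR, 94 held a miR-23b-3p site (17.3%), against 21.2% of other genes (Fisher's exact test, adjusted p = 0.0654), and of 728 rises 224 did (30.8%), against 20.4% (adjusted p = 9.67e-10). Of 28 measured published targets, 5 rose and 1 fell, and 7 rose and 4 fell when adjusted over the list alone (median 0.14, adjusted p = 0.164). With the trend removed, the ribosomal protein list still passed (adjusted p = 2.37e-07), but its median went from -0.532 to -0.294 and its falls from 17 to 9. The mesenchymal list passed too (adjusted p = 0.000117), with its median going from 0.382 to 0.307 and its rises from 7 to 6. Lists that no longer passed were integrin and laminin adhesion (6 of 31 rose), PI3K-AKT-mTOR (5 of 30 rose and 1 fell), RAS-MAPK (7 of 30 rose), TGF-beta (5 of 30 rose and 1 fell), small RNA machinery (4 of 23 rose), and the targets of miR-124-3p (7 of 35 rose) and of miR-218-5p (6 of 24 rose). Their adjusted p with the trend removed were 0.0952, 0.586, 0.0503, 0.408, 0.395, 0.056 and 0.248.

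**Figure D1:**
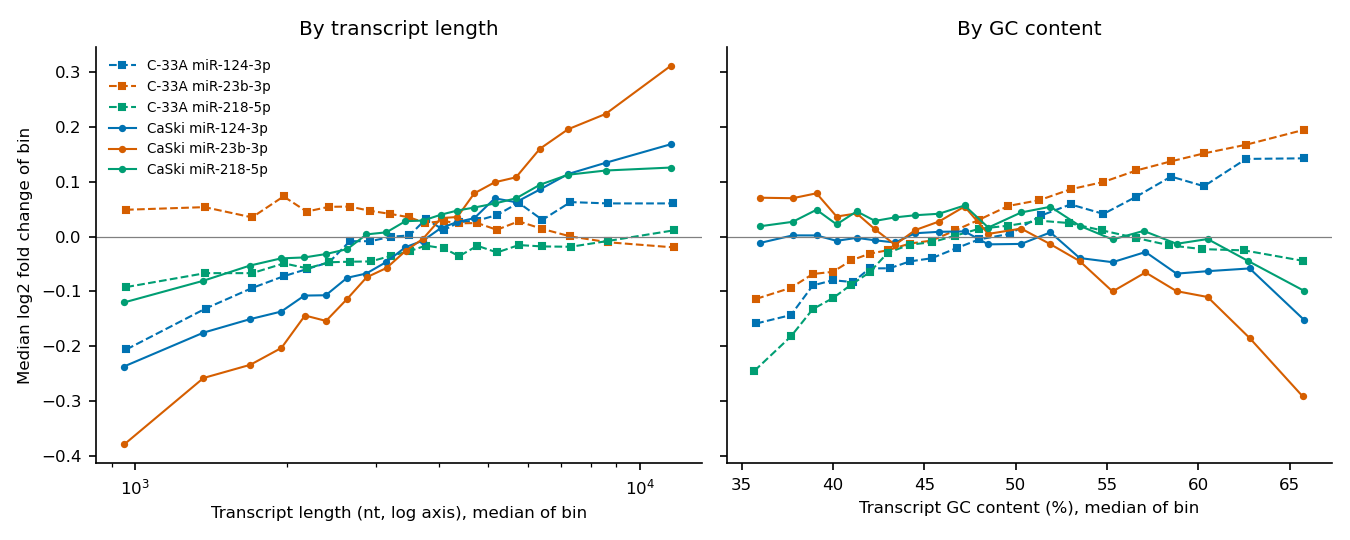
Median log2 fold change (vertical axis) of genes in 20 bins of transcript length in nt (left, log axis) or GC content in percent (right), for genes with an average log2 CPM of 2 or more; lines are the 6 comparisons, solid for CaSki and dashed for C-33A. CaSki with miR-23b-3p has the steepest course over length (Spearman rho 0.512), and C-33A with miR-23b-3p the steepest rise over GC content (rho 0.519).

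In CaSki with miR-218-5p, 13 genes fell and 2 rose. HMOX1, the inducible heme oxygenase, fell by 1.23 (SE 0.240, adjusted p = 0.00973), CETN2 by 0.96, VOPP1 by 0.92 and BIRC5 by 0.86 in the authors' deposited table. The rises were CALU, a calcium-binding protein of the secretory pathway, at 0.68, and MCFD2, a cargo receptor subunit, at 0.62 in the authors' deposited table. Of 24 measured published targets, 2 fell, none rose, and 3 fell when adjusted over the list alone (median -0.07, cameraPR adjusted p = 0.00078, and 0.0641 on ranks). With the trend removed the list had a median of -0.127 and 3 falls (adjusted p = 1.85e-05). Genes with a site shifted by -0.020 (SE 0.0076, permutation p = 0.00055), which turned to 0.013 with 6mer sites and was -0.067 with 8mer sites, -0.073 with matched 3' UTR length, -0.079 with the trend removed and -0.143 against the other 2 mimics, and 10 of 13 falls held a site (76.9%), against 15.3% of other genes. Ribosomal protein genes were lower with 0 of 31 called (median -0.175, adjusted p = 8.68e-05), with a median of -0.133 with the trend removed (adjusted p = 0.0239). Targets of miR-124-3p were higher with 0 of 35 called (median 0.121, adjusted p = 0.0189, 0.174 with a correlation of 0.05 and 0.363 with the trend removed). The 13 mitochondrially encoded genes were all higher in the 3 CaSki comparisons, with medians of 0.609, 1.484 and 0.606 after miR-124-3p, miR-23b-3p and miR-218-5p; 0 were called and the list did not pass (adjusted p = 0.62, 0.599 and 0.668). Across all comparisons 39 of 147 list tests passed. The median, the mean statistic and the test differed in sign in 24 tests, of which 0 passed. Fibroblast, leukocyte and endothelial markers, and keratinocyte differentiation genes in C-33A, had fewer than 5 measured members and were not tested. The 20 keratinocyte differentiation genes measured in CaSki did not pass (adjusted p = 0.0678, 0.479 and 0.991).

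**Figure D2:**
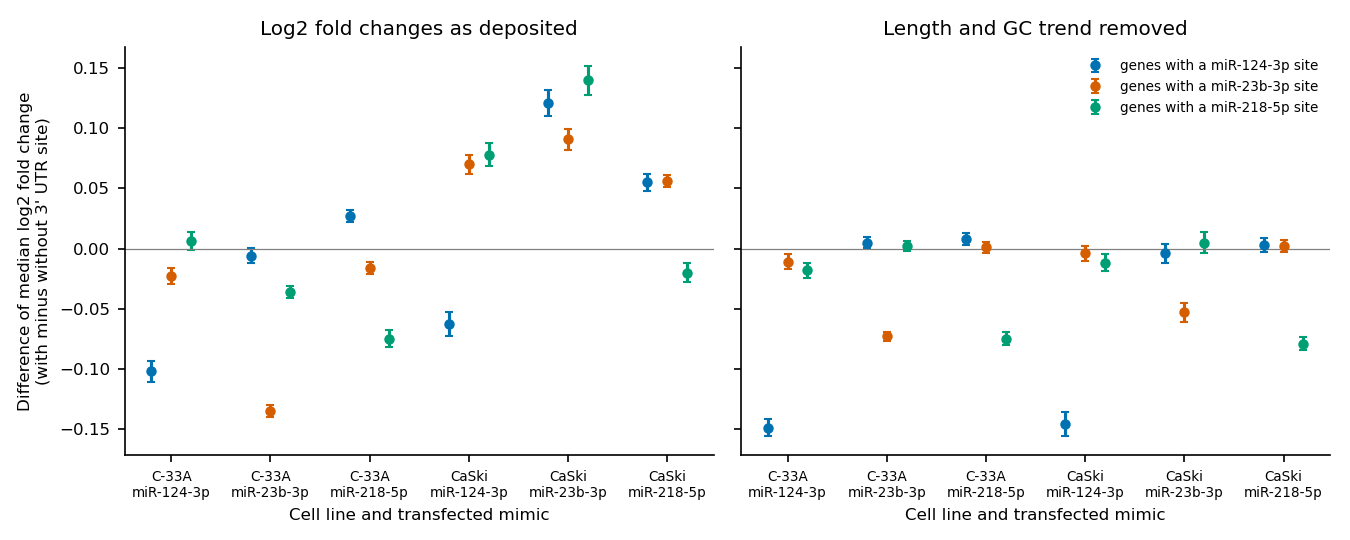
Difference of median log2 fold change between genes with and without a 3' UTR site (vertical axis) for each comparison (horizontal axis), with bootstrap SEs as bars; colours give the microRNA whose sites were counted, on deposited fold changes (left) and with the trend on length and GC content removed (right). On the right, sites of the transfected mimic lie between -0.149 and -0.053 and those of the other mimics between -0.018 and 0.008; this removal was chosen after seeing the data.

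The lines were then set side by side. After miR-124-3p, 43 genes fell in both lines, against 0.691 for independent lists (Fisher's exact test, p = 8.39e-71), and 6 rose in both. Pearson's r of the fold changes was 0.350 across 12970 genes, which are not independent replicates. CD164, ATL3, VAMP3, ITGB1, SERP1 and ATP6V0E1 led the shared falls. After miR-218-5p, 9 genes fell in both lines, against 0.032 for independent lists (Fisher's exact test, p = 2.5e-22), with GLCE, CETN2, VOPP1, BIRC5, TMEM64 and GNAI2 leading, and r was 0.236 across 12902 genes. No gene differed between the lines after miR-124-3p or miR-218-5p in the normal test of the difference with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 325 of 12970 and 201 of 12902 genes. Both counts lie below the share of 0.05 that no difference at all would give, so the test was conservative. The absence of calls therefore does not show that the lines responded alike. Over all genes with reads, with no filter on expression, r after miR-124-3p, miR-23b-3p and miR-218-5p was 0.007, -0.003 and -0.002.

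After miR-23b-3p, 7 genes fell in both lines, against 0.763 for independent lists (Fisher's exact test, p = 5.01e-06), and 0 rose in both. DDAH1, SEC23A, a coat protein of vesicles leaving the endoplasmic reticulum, B4GAT1, SMS, the spermine synthase, EIF4EBP2 and MSMO1 led these. Across 12905 genes r was 0.028. The fold changes of 220 genes differed between the lines, 120 higher and 100 lower in CaSki, and 22 with the trend on length and GC content removed. TRIB3, at 1.32 in C-33A and -0.15 in CaSki in the authors' deposited table, differed most by p (CaSki minus C-33A -1.47, SE 0.242, adjusted p = 1.63e-05). ATF4, the transcription factor of the integrated stress response, stood at 0.57 in C-33A and -0.63 in CaSki, and JDP2 at 0.92 and -0.63, in the authors' deposited table. The ER stress and integrated stress response list did not pass after miR-23b-3p in CaSki (median 0.118, cameraPR adjusted p = 0.233). There 4 of 25 members rose and 1 fell, ATF4.

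Within a line, the comparisons share the control libraries. In C-33A, r between pairs of mimics was 0.334, 0.377 and 0.400, against 0.443, 0.413 and 0.462 simulated for unchanged groups, and the covariances (0.0232, 0.025 and 0.021) lay below the simulated 0.0336, 0.0316 and 0.0328. The simulation thus gave more shared spread than was seen in C-33A, and its values may be too high there. It is an uncertain yardstick for CaSki too, where the recovered SEs rest on another degree of pooling. In CaSki, r was 0.782, 0.763 and 0.792, against a simulated 0.492, 0.501 and 0.495, and the covariances (0.1307, 0.0867 and 0.1135) lay above the simulated 0.0599, 0.0533 and 0.0596. These CaSki values rest on 15058, 15012 and 14988 genes. An average log2 CPM of 0 or more was met by 15148 genes in all 3 CaSki comparisons, so some expressed genes were left out of these correlations. After miR-124-3p and miR-23b-3p in CaSki, 19 genes fell in both and 26 rose in both, against 4.89 and 3.33 for independent lists. Part of any excess may come from the shared controls, which could not be split. CASTOR2 rose in 4 of the 6 comparisons, among them all those in C-33A, which share their control libraries and are not independent.

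**Figure D3:**
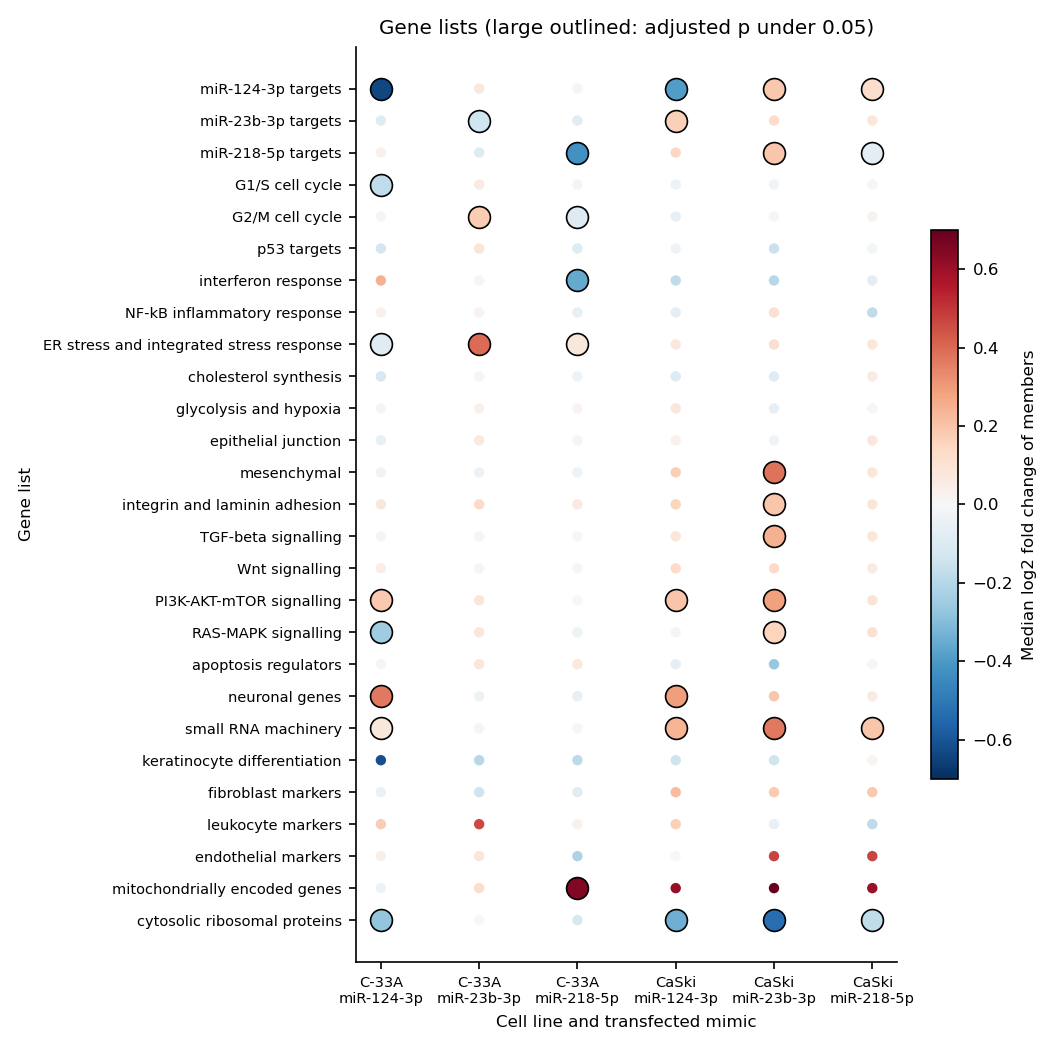
Median log2 fold change of the measured members (colour) of the gene lists reported here (vertical axis) in the 6 comparisons (horizontal axis); large outlined points passed the list test at an adjusted p under 0.05. Published targets of miR-124-3p were lower with their own mimic in both lines (-0.64 and -0.39); the mitochondrially encoded list in CaSki with miR-23b-3p lies past the end of the colour scale.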

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

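The tests chosen only after the result was seen were those of the trend as the whole cause, of a control library that stands apart, of miR-23b-3p sites among the CaSki falls, and of the genes far below all others in CaSki.

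The fold change after miR-23b-3p differed between the lines for 220 genes by a test of the difference itself. Those that differed most by p were TRIB3 (CaSki minus C-33A -1.47), ATF4 (-1.20), JDP2 (-1.55) and CEBPB (-1.18), each higher in C-33A. The ER stress and integrated stress response list as a whole was not lower after miR-23b-3p in CaSki. Its median there was 0.118, and 0.175 with the trend on length and GC content removed (cameraPR adjusted p = 0.233 and 0.0503).

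The number of genes called after miR-23b-3p in CaSki was the highest of the 6 comparisons; removal of the trend on length and GC content, over the same genes, left 878 of 2364 calls (a share of 0.371), but the count with new calls included was 1174 (0.497 of the calls before), and of the deposited calls a share of 0.498 was left. The same step left shares of 0.559, 0.419 and 0.487 in C-33A and 0.57 and 0.759 in the other CaSki comparisons. Of the deposited calls it left 0.789, 0.786 and 0.711 in C-33A and 0.861 and 1.0 in CaSki. By both shares the loss was largest after miR-23b-3p in CaSki, though not by the count with new calls included (0.435 after miR-23b-3p in C-33A). The 1174 calls left, against 332 in the next comparison, argue against the trend in the form fitted here as the whole cause. They do not bear on a trend of another form. In the contrast with the other 2 mimics, where the control libraries cancel, the trend with transcript length stayed (Spearman rho 0.418), which argues against a control library that stands apart as its whole cause. In the same contrast rho went from 0.405 to -0.064 after miR-124-3p and from 0.336 to -0.418 after miR-218-5p. The contrasts of a line cancel when added together, so these values depend on that after miR-23b-3p and are not separate evidence. The number of calls did not stay the highest: 364 genes were called in this contrast (111 fell, 253 rose), against 496 after miR-124-3p. These 364 are not simply the deposited calls that were left. Of the 609 deposited falls 56 were also called in the contrast, and of the 863 deposited rises 121 were. A control library that stands apart may thus account for part of the calls, as may changes common to the 3 mimics, which cancel too. Effects of miR-23b-3p enter the contrasts of the other mimics with reversed sign, so the ranking of these counts cannot decide the question. Called falls held a miR-23b-3p site more often than genes of like 3' UTR length (Mantel-Haenszel odds ratio 1.88, 95% interval 1.46 to 2.42), but not without regard to length (17.3% against 21.2%, odds ratio 0.776), so repression through sites may account for some falls, and the source of the others stays open.

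In the 3 CaSki comparisons, 411 genes stood at a log2 fold change of -5 or less, down to -17.41, and 0.0% of them were called, with median p of 0.232, 0.301 and 0.227. They include RPS18, CLIC1, TUBB and TAP1, chosen after their values were seen, and 96 of the 385 with a known position lie between 28837869 and 33418317 on chromosome 6 (GRCh38), around the HLA genes. The absence of calls argues against repression by the mimics. Of the 411 genes, 74.9% had no counted read in any C-33A comparison, against 2.53% of other genes with an average log2 CPM in CaSki between their lower quartile and their maximum, which is consistent with reads that match more than one reference sequence and were counted only in part of the CaSki control libraries. Without values per sample this remains a hypothesis. After miR-124-3p, miR-23b-3p and miR-218-5p in CaSki, 431, 497 and 442 genes stood below -5, and 4, 70 and 3 stood above 5. The control libraries are shared, so the hypothesis does not cover the larger number above 5 after miR-23b-3p. Its source was not tested.

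After miR-23b-3p in C-33A, 5 of 427 zinc finger genes fell, namely ZNF91, ZNF107, ZNF714, ZNF45 and ZNF678, chosen after their values were seen, and 4 of them held a 3' UTR site; 2 zinc finger genes fell with the trend on length and GC content removed. Among zinc finger genes without a 3' UTR site, those with 2 or more coding sites lay 0.098 below those with none (difference -0.098, SE 0.033, permutation p = 2e-05, trend removed), short of the bound set beforehand, so sites in the coding sequence may contribute but are left open. The same difference was 0.011 and -0.016 after the other mimics in C-33A and -0.11 after miR-23b-3p in CaSki (adjusted p = 0.0822), where it was -0.056 and -0.052 after the other mimics. The GC content trend is open too: the family's median differed from other genes by -0.042 before and -0.007 after the trend was removed, and the test decides nothing because the bound was met before the removal.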

How the results depend on the processing

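No paired analysis was possible because the deposited tables hold no values per sample. For the same reason leaving out replicates, a replicate block, other samples in the fit, another normalization, a DESeq2 fit, a pseudocount, an estimated correlation, split controls and other splits of the samples were listed in the design but not run. The trend removal, the adjustment over genes with a known length and GC content, the contrast with the other 2 mimics and the correlations without log2 fold changes beyond 5 were chosen after seeing the data. Counts are given in the order C-33A miR-124-3p, miR-23b-3p, miR-218-5p, then CaSki in the same order. Adjusted over genes with an average log2 CPM of 0 or more, 136, 37, 64, 216, 1128 and 15 genes fell and 39, 23, 6, 158, 1414 and 9 rose. Adjusted over those of 1 or more, 145, 39, 68, 237, 1137 and 17 genes fell and 45, 23, 6, 170, 1341 and 11 rose. At an FDR under 0.01, 51, 8, 28, 60, 266 and 2 genes fell and 8, 6, 1, 17, 481 and 0 rose. With a log2 fold change of at least 1 in size, 24, 1, 6, 21, 42 and 1 genes fell and 7, 6, 0, 15, 144 and 0 rose. With Bonferroni adjustment, 32, 6, 18, 35, 45 and 3 genes fell and 5, 6, 1, 5, 138 and 0 rose. Adjusted over the 6 comparisons together, 101, 35, 62, 129, 313 and 22 genes fell and 24, 23, 6, 68, 536 and 14 rose. Over genes with a known length and GC content, 143, 39, 70, 228, 1078 and 17 genes fell and 45, 23, 8, 188, 1286 and 12 rose. With the trend removed over these genes, 111, 18, 34, 211, 490 and 28 genes fell and 9, 9, 8, 121, 684 and 10 rose. Against the other 2 mimics, 198, 61, 99, 345, 111 and 130 genes fell and 81, 112, 31, 151, 253 and 106 rose. Of the deposited falls, 71, 13, 34, 101, 56 and 12 were also called there. Of the deposited rises, 8, 7, 1, 23, 121 and 1 were. Fewer or more genes adjusted over, or a stricter threshold, moved the counts by construction; for the trend removal and the contrast with other mimics the cause was not tested. The site shift turned to 0.053 after miR-124-3p and 0.013 after miR-218-5p in CaSki with 6mer sites, a set that includes the longer sites. After miR-23b-3p in CaSki it turned to -0.053 with the trend removed and -0.029 with matched 3' UTR length, while it was 0.028 against the other 2 mimics. Other site shifts kept their direction and side of the threshold under every alternative run. The cause was not tested. Between lines, the correlations after miR-124-3p, miR-23b-3p and miR-218-5p were 0.350, 0.028 and 0.236 as reported. They were 0.457, 0.067 and 0.351 at an average log2 CPM of 2 or more. They were 0.007, -0.003 and -0.002 over all genes with reads. They were 0.42, 0.011 and 0.346 as Spearman's rho. They were 0.327, 0.006 and 0.194 without genes with a site. They were 0.389, 0.031 and 0.266 without log2 fold changes beyond 5. They were 0.479, 0.135 and 0.427 as rho with the trend removed. With the trend removed, 1, 22 and 0 genes differed between lines. Between mimics, the correlations at an average log2 CPM of 2 or more were 0.305, 0.341, 0.393, 0.816, 0.782 and 0.844, C-33A first. Between mimics, the correlations as Spearman's rho were 0.339, 0.389, 0.381, 0.713, 0.633 and 0.697, C-33A first. Between mimics, the correlations with the trend removed were 0.181, 0.266, 0.324, 0.758, 0.736 and 0.81, C-33A first. The number of lists that passed was 8, 4, 5, 7, 10 and 5 as reported. It was 4, 3, 4, 5, 6 and 3 with a correlation of 0.05. It was 6, 4, 6, 8, 8 and 3 on ranks. It was 5, 3, 4, 3, 3 and 3 with the trend removed. The cause of these moves was not tested.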

Other observations

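Genes of the small RNA machinery were higher in the 3 CaSki comparisons, with medians of 0.24, 0.37 and 0.19 (cameraPR adjusted p = 0.00078, 0.000546 and 0.0213). These comparisons share their control libraries, so they are not independent, and after miR-218-5p the list did not pass with a correlation of 0.05 (adjusted p = 0.15) or on ranks (0.0729). After miR-23b-3p 4 of 23 members rose, and 10 rose and 1 fell when adjusted over the list alone, among the rises the Argonaute genes AGO1 (0.76), AGO2 (0.50) and AGO3 (0.55) in the authors' deposited table. With the trend on length and GC content removed, the adjusted p of the list was 0.217, 0.395 and 0.623, and after miR-23b-3p 0 members were called, with AGO1 at 0.40, AGO2 at 0.14 and AGO3 at 0.18 (adjusted p = 0.0521, 0.514 and 0.426).

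The stress response gene TRIB3, which rose after miR-23b-3p in C-33A, fell after miR-124-3p in C-33A (-1.01) and in CaSki (-0.84) in the authors' deposited table. In CaSki after miR-23b-3p it stood at -0.15. The mitochondrial rRNA gene MT-RNR2, chosen after its values were seen, stood at 1.18, 2.24 and 1.26 in the CaSki comparisons in the authors' deposited table, with no call and recovered SEs of 1.81, 2.42 and 1.81.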
